A study of Caenorhabditis elegans with 6 samples.

How the data were processed

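The data are gene-level read counts of 6 RNA sequencing libraries from whole C. elegans, 3 from nmr-2(ok3324) animals and 3 from N2 wild-type (WT) animals, all infected with S. aureus for 4 h at 25 °C after growth at 20 °C. Samples were placed in groups by the genotype and replicate number in their titles. Per the labels' protocols, total RNA was extracted with a column kit, treated with DNase and made into libraries by a standard Illumina procedure. The deposited values are counts: whole numbers of reads per gene, unnormalised, in 1 table per library, and the submitters' processing notes name HTSeq as the counting tool and DESeq2, with no versions or settings. The aligner, genome build, annotation release, strand setting and read filters are not given in the sources used here. Because the strand setting is unknown, reads from a gene and an overlapping or antisense partner cannot be separated, and genes with near-identical copies (among them hsp-16, vitellogenin, msp and histone genes) may share or lose reads.

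Each table lists the same 46911 WormBase gene identifiers, without summary lines for unassigned reads. Of these, 46863 were found in the WBcel235 annotation (Ensembl release 115), which supplied names and coordinates. The remaining 48 took at most 0.002% of a library, and 27060 identifiers had no read in any library. Coordinates are those of that annotation and not of the unstated build used for counting. Total counts ran from 19680710 to 25041171 per library. Intervals on single genes' reads cover counting error only. Pairs of libraries of a group differed by far more than sampling noise (chi-square per degree of freedom from 9.4 to 144.2 over genes with at least 20 reads), so none was counted as a duplicate.

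Differences between nmr-2 and WT were tested with edgeR 4.0.16 in R 4.3.3. Counts were filtered with filterByExpr on genotype, which kept 11379 genes, normalised by the trimmed mean of M values (TMM) and fitted with the quasi-likelihood model (robust dispersion and fit, genotype as the only term). Adjusted p-values follow Benjamini and Hochberg, with a threshold of 0.05. Fold changes are nmr-2 minus WT on the log2 scale, and their standard errors were taken from the fitted coefficient and the F statistic. CPM values are TMM-normalised and given as mean ± SD of 3 libraries. The sums of msp and cpg genes and the level of col-19 are given per library without TMM scaling. Principal components and Spearman correlations used log2 CPM with a prior count of 2.

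A set of 35 gene lists was tested with camera (limma 3.58.1) on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the lists. They cover immunity (S. aureus response, PMK-1 targets and components, lysozymes, C-type lectins, antimicrobial peptides, intracellular pathogen response, lysosome and autophagy), stress and metabolism (endoplasmic reticulum and mitochondrial unfolded protein responses, abu and pqn genes, heat shock, oxidative stress, DAF-16 targets, detoxification, lipid metabolism) and stage and germline (collagens, moulting, sperm, oocyte and eggshell, vitellogenins, germline). They also cover tissues and neurons (intestine, body wall muscle, pharynx, pan-neuronal, transmitter identity, neuropeptides, glutamate signalling, Wnt and muscarinic signalling, chemoreceptors) and ribosomal proteins, histones, mitochondrially encoded genes and F-box genes. Alternatives were camera with the correlation estimated per list, and fry. With the preset correlation camera takes its degrees of freedom from the number of genes. With an estimated correlation it takes them from the 6 libraries, so the preset p-values are the smaller. Members were matched by symbol, symbol pattern or sequence name, and the lists were drawn up from general knowledge of the field, independently of these libraries. The lists, the tests and the first set of alternatives were fixed before the data were examined.

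The rule for naming genes was fixed in the same way. It takes nmr-2, then the 12 highest and 12 lowest log2 fold changes among genes with adjusted p under 0.05, a mean log2 CPM of at least 2 and no overlap between the groups (only 9 met it on the higher side). It adds a panel of 18 genes whatever their test: fmo-2, clec-60, clec-52, ilys-3, lys-5, cyp-37B1, exc-5, sysm-1, irg-4, irg-5, pmk-1, hlh-30, nmr-1, glr-1, hsp-4, gst-4, sod-3 and mtl-1. For each list it adds up to 4 members with the smallest adjusted p, or up to 3 with the largest mean where none was called. Of the genes so named, nmr-2 and glr-1 were below the filter and the other 118 were tested.

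The share of tested genes called near nmr-2 (2 Mb, with 1 and 5 Mb as alternatives) and on each chromosome was compared with the rest by Fisher's exact test, two-sided. That first set held a replicate block, leaving out each library in turn, normalisation by DESeq2's size factors (RLE) or upper quartile, no filter beyond 1 read, a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom and edgeR's test against a 1.5-fold change. Removing ribosomal RNA genes, using the log2 ribosomal RNA share as a covariate and the settings for chromosome V were added after the data were seen. Replicate numbers are shared between the groups, but the labels do not say that they mark a batch, so the fit reported has no block.

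The procedure was tested on simulated counts with the means, dispersions and library sizes of these libraries, over 11251 genes. It recovered 64.2%, 88.1% and 100% of genes changed by 1.5-, 2- and 4-fold in the simulated comparison of nmr-2 with WT, with 8 false calls among 191. The changed genes were drawn from better expressed genes only, so recovery of weakly expressed genes is not known. A simulated shifted list was called and 0 of 30 unchanged lists were. Genes were simulated independently of one another, so this says nothing about false calls of lists whose members move together. No simulated library carried a shift shared by many genes, as nmr-2 replicate 2 did. The recovery and false calls may therefore differ in the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.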

Results

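Whole Caenorhabditis elegans infected with the Gram-positive pathogen Staphylococcus aureus were profiled by RNA sequencing in 6 libraries. Of these, 3 came from animals carrying nmr-2(ok3324), an allele of the gene for an NMDA-type ionotropic glutamate receptor subunit, and 3 came from the N2 wild type (WT). Animals of both genotypes were raised at 20 °C to the last larval stage (L4) and then kept on the pathogen for 4 h at 25 °C. The labels do not give a stage at collection. Uninfected animals were not analysed here, so every difference reported below is between infected mutant and infected WT animals and none is a response to infection. The nmr-2 libraries held 19924551, 20063610 and 22445497 counted reads, and the WT libraries 19942550, 25041171 and 19680710. A read was counted for 16598, 15025 and 15994 genes in nmr-2 replicates 1 to 3, and for 15769, 17156 and 16248 genes in the WT replicates. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

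The WT libraries resembled one another closely, while 1 mutant library stood apart. Spearman correlations of log2 library-scaled counts (CPM) over the 11379 tested genes lay between 0.9948 and 0.9952 for the WT pairs. They were 0.9947 for nmr-2 replicates 1 and 3, but 0.9868 and 0.9905 for replicate 2 against replicates 1 and 3. In nmr-2 replicate 2, ribosomal RNA genes took 7.48% of the reads, against 1.57% and 0.603% in the other nmr-2 libraries and 0.199%, 0.329% and 0.66% in WT. The first principal component, with 52.8% of the variance, placed that library at 50.6 and the other 5 between −25.4 and 7.4. The second, with 21% of the variance, placed WT between 6 and 14.8 and the nmr-2 replicates at −26.3, 7.3 and −15.7.

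The targeted gene, nmr-2 (WBGene00003775), lies on the minus strand of chromosome V from 15006341 to 15011660 in the WBcel235 annotation. Its reads were few in whole animals of either genotype. The nmr-2 libraries held 2, 2 and 0 reads in the gene and the WT libraries 6, 4 and 1. Pooled, that is 4 reads against 11, a ratio of 0.377 per counted read (95% exact interval 0.087 to 1.27, exact p = 0.119, two-sided, counting error only). The direction goes with the labels, but a difference was not detectable at this depth. The part of the gene removed by the allele is not given in the labels, so reads from the remaining exons cannot be separated, and the gene fell below the expression filter. The transcript of the partner subunit nmr-1 was also scarce, at 0.538 ± 0.295 CPM in nmr-2 and 0.812 ± 0.0121 CPM in WT (SD, n = 3 each; edgeR adjusted p = 0.631). The AMPA-type subunit gene glr-1, which was not tested, had 3, 0 and 1 reads in the nmr-2 libraries and none in WT.

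Genes that differed were mainly lower in infected nmr-2 animals than in infected WT animals. In edgeR's test 92 genes fell and 12 rose. The strongest decrease was in lbp-3, which encodes a protein of the fatty-acid-binding family. Its level was 2.27 ± 1.06 CPM in nmr-2 and 28.9 ± 3.4 CPM in WT (SD, n = 3 each), a log2 fold change of −3.64 ± 0.26 (SE; edgeR adjusted p = 1.41e-04). The prolyl carboxypeptidase-like gene pcp-3 was at 2.46 ± 0.739 against 23.7 ± 1.71 CPM, 9.44-fold higher in WT (edgeR adjusted p = 5.99e-05). The uncharacterised gene F38A5.2 was at 26.3 ± 4.6 against 120 ± 7.46 CPM, 4.55-fold higher in WT at the same adjusted p in edgeR.

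The other 9 of the 12 lowest genes were as follows. The palmitate desaturase gene fat-5 fell by 1.93 on the log2 scale (SE 0.24, edgeR adjusted p = 0.00467). The S-adenosylmethionine synthetase gene sams-1 fell by 1.82 (SE 0.17, edgeR adjusted p = 8.86e-04), from 25 ± 4.65 CPM in WT to 7.05 ± 1.12 CPM. The lysosomal lipase gene lipl-3 fell by 1.69 (SE 0.18, edgeR adjusted p = 0.00213). The rest were gid-7, a homologue of a ubiquitin ligase subunit, the acyltransferase-like gene oac-14, the C-type lectin gene clec-70, F58G6.7, ZK593.3 and the pseudogene W06A11.4. Their log2 fold changes ran from −1.98 for W06A11.4 to −1.52 for clec-70.

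Only 9 genes met the same rule in the other direction. They were led by Y39G10AL.1, at 5.98 ± 2.2 against 1.79 ± 0.418 CPM (log2 fold change 1.74 ± 0.32, edgeR adjusted p = 0.037), and by dod-24, a gene downstream of the FOXO factor DAF-16, which rose by 1.35 (SE 0.17, edgeR adjusted p = 0.00494) from 4.62 ± 0.258 CPM in WT. The collagen genes col-96, col-101 and col-124 rose by 1.34, 1.27 and 1.15. The glutathione S-transferase gene gst-20 rose by 1.22 (SE 0.13, edgeR adjusted p = 0.00213). The F-box gene fbxa-107, the glucuronosyltransferase gene ugt-64 and the cysteine synthase-like gene cysl-2 rose by 0.81, 0.73 and 0.70.

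**Figure D1:**
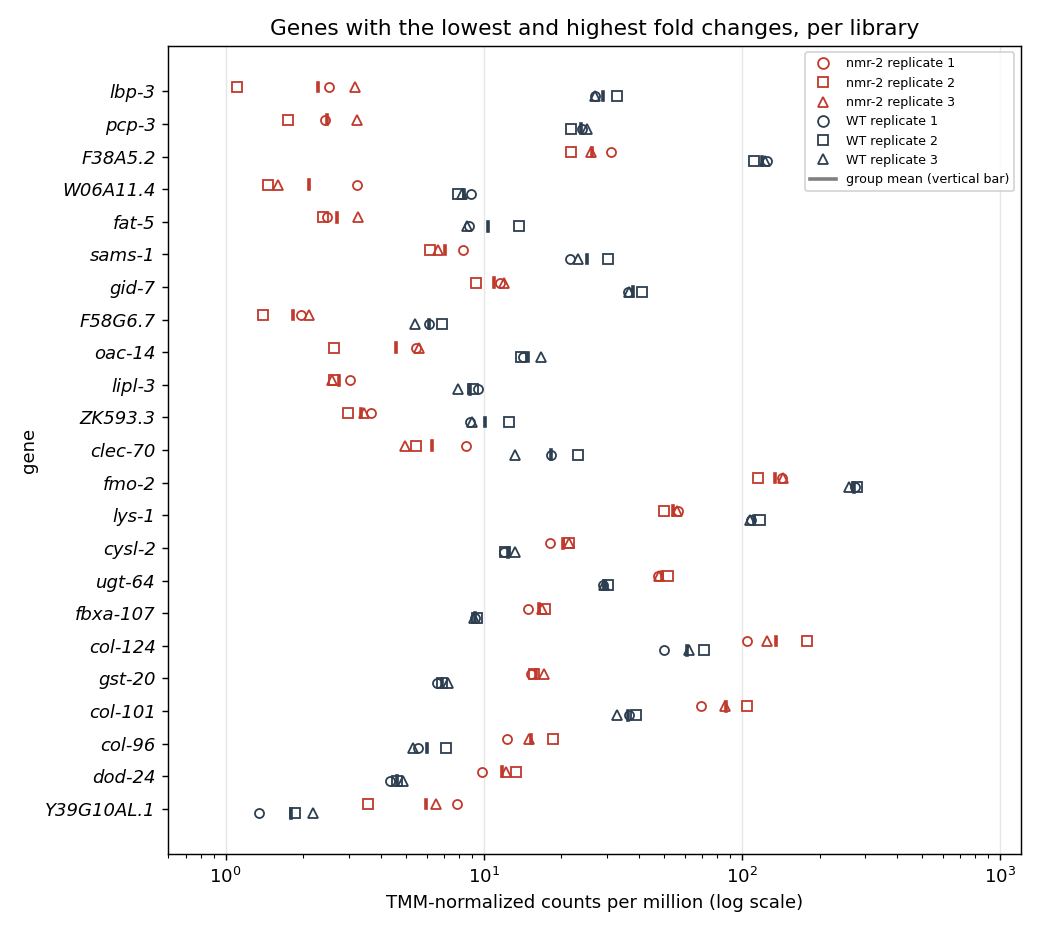
TMM-normalized CPM (x axis, log scale) of the 12 genes with the lowest and the 9 genes with the highest fold changes, and of fmo-2 and lys-1, in each library. Red symbols are nmr-2 libraries, dark symbols are WT libraries, symbol shape gives the replicate and vertical bars are group means; in each of these genes the 3 nmr-2 libraries lie on 1 side of the 3 WT libraries, as for lbp-3 with means of 2.27 and 28.9.

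In all, edgeR's quasi-likelihood test called 12 genes higher and 92 lower in nmr-2 among 11379 (Benjamini-Hochberg adjusted p under 0.05), so that 88.5% of the changed genes were lower. Of these, 61 differed by at least 2-fold, 9 higher and 52 lower, and 1421 genes had an unadjusted p under 0.05. In each of the changed genes every nmr-2 library lay beyond every WT library, as did 19.6% of all tested genes, where chance gives 10%. The count moved with single libraries. It was 489 (135 higher, 354 lower) without nmr-2 replicate 2, 174 without nmr-2 replicate 1, 44 without nmr-2 replicate 3, 71 without WT replicate 1 (with 6 rather than 12 higher), 33 without WT replicate 2 and 34 without WT replicate 3. The call was kept by 103 of the changed genes without nmr-2 replicate 2, and 29 genes (5 higher, 24 lower) were called in all 6 of these fits. Among the named ones, lbp-3, pcp-3, F38A5.2, fat-5, sams-1, gid-7, lipl-3, ZK593.3, dod-24, col-101, gst-20 and ugt-64 were among those 29. By contrast, F58G6.7 was called in 5 of the 6 fits, oac-14 and col-96 in 4, W06A11.4 in 3, and clec-70, Y39G10AL.1, col-124, fbxa-107 and cysl-2 in 2.

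Genes known to be induced by S. aureus in WT worms were lower in infected nmr-2 animals. Of 22 tested members, 7 fell and none rose, and 18 had a fold change below 0. The clearest was fmo-2, the flavin-containing monooxygenase gene used as a marker of the response to this pathogen, which was at 134 ± 16.6 CPM in nmr-2 and 271 ± 10.1 CPM in WT, 2.02-fold higher in WT (SD, n = 3 each; log2 fold change −1.01 ± 0.10, edgeR adjusted p = 0.00155). It lies on chromosome IV from 10682524 to 10684367 and was called in each of the 6 fits that left out a library. The lectin genes clec-41 and clec-70 fell by 0.74 and 1.52, and the lysosomal lipase genes lipl-3 and lipl-5 by 1.69 and 0.47. The list had a median log2 fold change of −0.62 (camera, adjusted p = 1.72e-08; adjusted p = 0.196 with an estimated correlation). Adjusted over the list alone, 10 members were lower and 1 higher. Not all known members passed the test. Below 0 without a call were clec-60 (−0.45, edgeR adjusted p = 0.552), ilys-3 (−0.55, 0.48), lys-5 (−0.71, 0.343) and cyp-37B1 (−0.21, 0.345). Above 0 without a call were exc-5 (0.07, 0.909) and clec-52 (0.87, 0.307). Without nmr-2 replicate 2 the list had a median of −0.52, with 8 lower and 1 higher of 23 tested. The call of clec-41 was lost in 3 of the 6 fits that left out a library (highest adjusted p 0.108, without WT replicate 2), that of clec-70 in 4 (0.177, without nmr-2 replicate 2) and that of lipl-5 in 5 (0.217, without WT replicate 2).

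Lysozyme genes were lower across the family, with all 13 tested members below 0. The best expressed of those that passed the test, lys-1, was at 54.2 ± 3.68 CPM in nmr-2 and 111 ± 5.88 CPM in WT (log2 fold change −1.03 ± 0.09, edgeR adjusted p = 5.06e-04), and it lies on chromosome V from 10277904 to 10279056. The genes lys-2 (−0.83) and lys-10 (−2.83, from 1.62 ± 0.268 to 0.218 ± 0.131 CPM) fell as well, so that 3 members passed over all genes and 9 when adjusted over the list alone. The list had a median of −0.79 (camera, adjusted p = 1.25e-08; adjusted p = 0.196 with an estimated correlation). The S. aureus list shares 4 tested genes with the lysozymes and 4 with the C-type lectins. Its 14 other members had a median of −0.47, 11 of them below 0 and 5 of them lower in the test. The call of lys-1 held in all 6 fits that left out a library, whereas lys-2 and lys-10 were each lost without nmr-2 replicate 3 (adjusted p = 0.129 and 0.117 in edgeR), WT replicate 2 or WT replicate 3.

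C-type lectins, which bind carbohydrates and include many pathogen-induced genes, were lower as a group. Of 70 tested, 5 fell and none rose, among them clec-218 (−1.16) and clec-186 (−0.90), and 53 lay below 0. The median was −0.31 (camera, adjusted p = 5.49e-05; adjusted p = 0.51 with an estimated correlation), and adjusted over the list alone 11 were lower and 1 higher. The median was −0.17 without WT replicate 2 (camera, adjusted p = 0.00275). Antimicrobial peptide genes went both ways. The thaumatin-like gene thn-2 fell from 51.9 ± 2.72 to 28.9 ± 1.74 CPM (log2 fold change −0.84 ± 0.09, edgeR adjusted p = 0.00213), and the caenacin gene cnc-2 and the fungus-induced gene fip-5 fell by 2.57 and 1.98 at levels below 5 CPM. The other 37 of 40 tested members did not pass. This list's median was 0.01 while its mean was −0.14 and camera's direction was down (adjusted p = 0.376; adjusted over the list alone, 4 lower and 2 higher). It was −0.23 without nmr-2 replicate 1 and, with camera's direction up, 0.07 without nmr-2 replicate 2 and 0.13 without WT replicate 2. The calls of clec-218, clec-186 and fip-5 were each lost in 4 of the 6 fits that left out a library and that of cnc-2 in 3, with highest adjusted p of 0.129, 0.195, 0.208 and 0.0767 in edgeR, while thn-2 was called in all 6.

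The p38 MAP kinase branch of immunity showed no common direction. Among 17 tested genes known to need the kinase PMK-1, dod-24 rose and lys-2 fell, and the median was −0.28 (camera, adjusted p = 0.684; adjusted over the list alone, 1 lower and 2 higher). It was −0.06 without WT replicate 2, with camera's direction up. The reporter gene sysm-1 was at 2.11 ± 0.975 against 3.16 ± 1.12 CPM (edgeR adjusted p = 0.562), irg-4 at 2.86 ± 0.539 against 4.36 ± 0.791 CPM (0.333) and irg-5 at 0.856 ± 0.371 against 0.778 ± 0.262 CPM (0.941). None of the 12 pathway components passed, over all genes or adjusted over the list alone (median −0.06; camera, adjusted p = 0.427), with pmk-1 at 12.4 ± 2.16 against 11.4 ± 1.46 CPM (edgeR adjusted p = 0.765) and skn-1, atf-7 and dkf-2 at log2 fold changes of 0.06, −0.09 and −0.07. The intracellular pathogen response genes, which answer viruses and microsporidia, gave no call among 20 tested (median −0.15; camera, adjusted p = 0.25; adjusted over the list alone, 2 lower), with pnp-1, drh-1 and skr-4 at −0.10, 0.13 and −0.35. That median was −0.40 without nmr-2 replicate 1, −0.04 without nmr-2 replicate 2 and −0.07 without WT replicate 2.

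In the lysosome and autophagy list 3 genes passed. The lipase genes lipl-3 and lipl-5 fell, and the cathepsin L gene cpl-1 fell from 770 ± 27.8 to 536 ± 45.7 CPM (log2 fold change −0.52 ± 0.10, edgeR adjusted p = 0.0427). The list had 53 tested members, whose median was −0.04 (camera, adjusted p = 0.0944; adjusted over the list alone, 4 lower). The gene for the regulator HLH-30, the TFEB homologue that drives lysosomal and S. aureus-induced genes, was at 82.2 ± 13.4 against 97.1 ± 6 CPM (edgeR adjusted p = 0.448). The call of cpl-1 was lost in 4 of the 6 fits that left out a library, with a highest adjusted p of 0.231 in edgeR without WT replicate 2.

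Lipid metabolism genes lay lower, led by the fatty-acid-binding gene lbp-3 and the desaturase gene fat-5. These 2 of 37 tested members passed over all genes and 9 did so, all lower, when adjusted over the list alone. The median was −0.25 with 28 members below 0 (camera, adjusted p = 1.75e-04; adjusted p = 0.51 with an estimated correlation). The list had 9 lower members and a median of −0.14 without nmr-2 replicate 2, and a median of −0.11 without WT replicate 2. Of the 17 tested targets of DAF-16, fat-5 and the glyoxylate cycle gene icl-1 fell, the latter from 1180 ± 24.6 to 775 ± 75.1 CPM (log2 fold change −0.60 ± 0.11, edgeR adjusted p = 0.0304). The median of that list was −0.06 (camera, adjusted p = 0.955; adjusted over the list alone, 2 lower and 1 higher), turning to 0.10 without nmr-2 replicate 2 and 0.13 without WT replicate 2, with sod-3 at 0.24 and mtl-1 at 0.15 (edgeR adjusted p = 0.847 and 0.794). The call of icl-1 was lost in 4 of the 6 fits that left out a library (highest adjusted p 0.193, without WT replicate 2).

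Detoxification genes changed in both directions. Among 111 tested cytochrome P450, glucuronosyltransferase and glutathione S-transferase genes, 7 fell and 2 rose. The glucuronosyltransferase gene ugt-62 fell from 46.6 ± 2.36 to 21.8 ± 0.677 CPM (log2 fold change −1.09 ± 0.09, edgeR adjusted p = 4.14e-04) and ugt-43 fell by 1.73, while ugt-64 and gst-20 rose. The median was −0.14 (camera, adjusted p = 0.0029; adjusted p = 0.573 with an estimated correlation), with 13 lower and 4 higher adjusted over the list alone. It was −0.22 without nmr-2 replicate 1 and −0.09 without nmr-2 replicate 2, and stayed called in both (adjusted p = 0.00389 and 0.0417). The calls of ugt-62, ugt-64 and gst-20 held in all 6 fits that left out a library, and that of ugt-43 was lost without any 1 of the WT replicates (highest adjusted p 0.107, without WT replicate 2).

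In the stress lists given here, only 2 small heat shock genes passed over all genes. The small heat shock genes hsp-16.41 and hsp-16.2 fell by 1.44 and 1.18, to 6.43 ± 2.51 and 5.36 ± 1.46 CPM in nmr-2 (edgeR adjusted p = 0.0281 and 0.0366), as 2 of 18 tested heat shock genes. Both belong to a set of near-identical copies, so their separate counts are uncertain. The list's median was 0.03 while its mean was −0.11 and camera's direction was down (adjusted p = 0.785; adjusted over the list alone, 3 lower). Oxidative stress genes and targets of SKN-1 were slightly higher as a group, with 20 of 25 tested members above 0 and none called over all genes or adjusted over the list alone. Their median was 0.14 (camera, adjusted p = 0.00647; adjusted p = 0.313 with an estimated correlation), and 0.07 and 0.09 without WT replicate 2 or 3. Examples are the peroxiredoxin gene prdx-2 at 0.25, the catalase gene ctl-2 at 0.19, trxr-1 at 0.04 and gst-4 at −0.26 (edgeR adjusted p = 0.328, 0.442, 0.875 and 0.677). No member passed among 24 endoplasmic reticulum unfolded protein response genes (median −0.02; camera, adjusted p = 0.588), where the chaperone gene hsp-4 was at 405 ± 89.6 against 412 ± 19.3 CPM (edgeR adjusted p = 0.949) and crt-1, pdi-3 and cdc-48.1 were at −0.20, −0.21 and 0.01. The 34 abu and pqn genes (median −0.04; camera, adjusted p = 0.401) and the 14 mitochondrial unfolded protein response genes (median −0.02; camera, adjusted p = 0.955) held none either, with pqn-59 at 0.01 and hsp-6 and hsp-60 at −0.04 and −0.51. Adjusted over the list alone, 1 mitochondrial member was lower. The calls of hsp-16.41 and hsp-16.2 were lost in 3 and 4 of the 6 fits that left out a library (highest adjusted p 0.169 and 0.195, both without WT replicate 3).

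Yolk protein genes were lower in nmr-2, while cuticle genes went both ways. All 6 vitellogenin genes lay below 0, and vit-4 fell from 2810 ± 330 to 1520 ± 302 CPM (log2 fold change −0.89 ± 0.16, edgeR adjusted p = 0.0304), although reads of vit-3, vit-4 and vit-5, which are near-identical, may be divided among them. The list had a median of −0.34 (camera, adjusted p = 4.88e-04; adjusted p = 0.51 with an estimated correlation), with 3 members lower adjusted over the list alone. Without nmr-2 replicate 2 its median was −0.54 and all 6 members were lower. Of 67 tested collagen genes, col-96, col-101 and col-124 rose and col-169 fell by 2.87 from a level of 0.734 ± 0.182 CPM. The collagen median was −0.35 (camera, adjusted p = 0.119; adjusted over the list alone, 13 lower and 12 higher), and the list was called lower without nmr-2 replicate 2 (median −0.49, adjusted p = 0.00325), nmr-2 replicate 3 (−0.77, 0.0059) or WT replicate 1 (−0.81, 1.02e-08). Moulting genes had a median of −0.44 over 20 tested members with no gene called (camera, adjusted p = 0.0029; adjusted p = 0.687 with an estimated correlation; adjusted over the list alone, 3 lower), with nhr-23, noah-1 and nas-37 at 0.08, −0.44 and −0.43. The moulting call was lost without nmr-2 replicate 2 (median −0.30, adjusted p = 0.0799) or WT replicate 2 (−0.23, 0.0724), while its median was −0.73 without nmr-2 replicate 1. The calls of vit-4 and col-169 were each lost in 4 of the 6 such fits (highest adjusted p 0.187 and 0.26 in edgeR, both without nmr-2 replicate 3).

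Germline lists moved with single libraries. All 14 tested sperm genes lay below 0, with a median of −1.12 and no gene called (camera, adjusted p = 6.73e-04; adjusted p = 0.51 with an estimated correlation), and their best expressed members spe-44, spe-15 and ssp-37 were at −0.06, −0.08 and −0.46. The median of the sperm genes relative to the WT mean was −0.54, −1.61 and −1.01 in the nmr-2 replicates, and −1.07, 0.35 and 0.55 in WT, so that WT replicate 1 lay among the mutant libraries. The sperm median was −2.93, −2.15 and −2.15 without nmr-2 replicate 1, 2 or 3 and −2.96 without WT replicate 1, with other genes past the filter in each. Oocyte and eggshell genes had a median of 0.14 over 24 tested members (camera, adjusted p = 0.00844; adjusted p = 0.81 with an estimated correlation), and cbd-1, cpg-2 and cey-2 were at 0.17, 0.21 and −0.06. Germline proliferation and meiosis genes had a median of 0.08 over 28 (camera, adjusted p = 0.0405; adjusted p = 0.81 with an estimated correlation), and gld-1, wago-1 and rnr-1 were at 0.01, 0.05 and 0.15. No member of these 3 lists passed, over all genes or adjusted over the list alone. Without nmr-2 replicate 2 the oocyte median was 0 (adjusted p = 0.928) and the germline median −0.01 (0.818), and both calls were also lost without WT replicate 2 (medians 0.10 and 0.03, camera adjusted p = 0.106 and 0.353). Leaving out nmr-2 replicate 1 gave medians of 0.25 and 0.15.

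Lists of housekeeping transcripts followed the library rich in ribosomal RNA. Cytosolic ribosomal protein genes had a median of 0.07 over 74 tested members (camera, adjusted p = 0.00759; adjusted p = 0.81 with an estimated correlation), with rpl-3 at 4460 ± 1140 against 4210 ± 102 CPM and rpl-4 and rpl-2 at 0.07 and 0.02 on the log2 scale. Histone genes, many of which are near-identical copies, had a median of 0.19 over 24 (camera, adjusted p = 0.0029; adjusted p = 0.51 with an estimated correlation), with his-72, his-74 and his-24 at 0.10, 0.13 and −0.21. Without nmr-2 replicate 2 these medians were −0.08 (adjusted p = 0.0887) and 0.10 (0.107), and without nmr-2 replicate 1 they were 0.19 and 0.32. The 13 mitochondrially encoded genes had a median of −0.07 (camera, adjusted p = 0.349), with COX3 at −0.14 and the mitochondrial genes MTCE.26 and MTCE.21 at −0.05 and 0.20. Their median was −0.34 and 6 fell without nmr-2 replicate 2 (camera, adjusted p = 5.24e-07). In the fit with all libraries no member of the 3 lists passed, over all genes or adjusted over the list alone.

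Among tissue markers, 1 gene passed. Among 21 intestinal markers the cathepsin B-like gene cpr-6 fell from 1020 ± 52 to 705 ± 33.1 CPM (log2 fold change −0.53 ± 0.10, edgeR adjusted p = 0.0379), and the list's median was −0.12 (camera, adjusted p = 0.0628; adjusted over the list alone, 4 lower and 1 higher). None passed among 20 body wall muscle markers (median 0.08; camera, adjusted p = 0.495), with unc-54, act-4 and unc-15 at 0.22, 0.15 and 0.06, or among 7 pharyngeal markers (median 0.28; camera, adjusted p = 0.134), with pha-4, gsnl-1 and tni-4 at −0.21, 0.33 and 0.28. The intestinal list was called lower without nmr-2 replicate 2 (−0.11, camera adjusted p = 0.0174) or WT replicate 3 (−0.10, 0.0491), and the pharyngeal list was called higher without WT replicate 2 (0.35, 0.0124). The muscle median ran from 0.01 without nmr-2 replicate 2 to 0.20 without nmr-2 replicate 1. The call of cpr-6 was lost in 4 of the 6 fits that left out a library (highest adjusted p 0.222, without WT replicate 2).

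Neuropeptide genes were lower as a group, while markers of the nervous system as a whole gave no call. Of 58 tested neuropeptide genes 47 lay below 0, none passed over all genes or adjusted over the list alone, and the median was −0.38 (camera, adjusted p = 3.30e-05; adjusted p = 0.51 with an estimated correlation), or −0.24 without WT replicate 2. Their best expressed members nlp-40, flp-6 and flp-28 were at −0.12, −0.41 and 0.05 (edgeR adjusted p = 0.641, 0.12 and 0.892). Pan-neuronal markers had a median of −0.06 over 24 members (camera, adjusted p = 0.0944; adjusted over the list alone, 2 lower; −0.16 without nmr-2 replicate 1, −0.14 without WT replicate 3 and −0.03 without WT replicate 2), with snb-1, maco-1 and unc-11 at −0.03, 0.30 and −0.03. In the glutamate signalling list, unc-43, the gene for calcium/calmodulin-dependent kinase II, fell from 81.3 ± 7.71 to 55.3 ± 6.28 CPM (log2 fold change −0.56 ± 0.11, edgeR adjusted p = 0.0489). It was the only one of 17 tested members to pass over all genes, and 2 were lower adjusted over the list alone. That list's median was −0.27 (camera, adjusted p = 0.00647; adjusted p = 0.573 with an estimated correlation), and its call was lost without nmr-2 replicate 2 (−0.14, adjusted p = 0.131), WT replicate 2 (−0.17, 0.0724) or WT replicate 3 (−0.30, 0.06), while the median was −0.45 without nmr-2 replicate 1. The call of unc-43 was lost in 4 of the 6 such fits (highest adjusted p 0.231 in edgeR, without WT replicate 2).

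The other neuronal and receptor lists held few calls. Transmitter identity genes had none among 10 (median −0.23, or −0.06 without WT replicate 2; camera, adjusted p = 0.349), with tdc-1, tbh-1 and cat-4 at 0.25, 0.26 and 0.03. Wnt and muscarinic signalling genes had none among 17, with mom-5, hmp-2 and mom-2 at 0.06, 0.18 and 0.25, and their median of −0.06 and mean of −0.03 lay below 0 while camera's direction was up (adjusted p = 0.684). The median was −0.25 without nmr-2 replicate 1 and 0.05 without nmr-2 replicate 2. Neither list held a call adjusted over the list alone. The chemoreceptor list was drawn up by symbol pattern alone (names starting with sr), so it may hold genes that are not receptors. Of its 34 tested genes, srdh-1 and srlf-34 fell by 0.54 and 1.66 (edgeR adjusted p = 0.041 and 0.048). Whether either encodes a receptor was not checked. The list had a median of −0.07 (camera, adjusted p = 0.0101, or 0.322 with an estimated correlation) and 5 lower members adjusted over the list alone. The chemoreceptor call was lost without nmr-2 replicate 1 (−0.21, adjusted p = 0.135) or nmr-2 replicate 2 (−0.11, 0.0799) and kept without nmr-2 replicate 3 (−0.19) or WT replicate 1 (−0.13). The calls of srdh-1 and srlf-34 were lost in 4 and 5 of the 6 such fits. Among 211 F-box and MATH-BTB genes, fbxa-6 fell from 5.4 ± 0.378 to 0.475 ± 0.301 CPM (log2 fold change −3.44 ± 0.36, edgeR adjusted p = 0.00174) and fbxa-107 rose, with a median of −0.02 (camera, adjusted p = 0.955; adjusted over the list alone, 2 lower and 2 higher). Without nmr-2 replicate 2 that list was called higher (median 0.06, adjusted p = 0.00285).

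Of the 35 gene lists, camera with its preset correlation called 11 lower and 5 higher, and none was called with an estimated correlation. The rotation test fry, which asks whether the genes of a list move on balance in 1 direction, called the S. aureus response genes and the lysozymes lower (adjusted p = 0.00631 for both) and the oxidative stress genes higher (adjusted p = 0.00403). Its test for change in either direction called 18 lists.

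**Figure D2:**
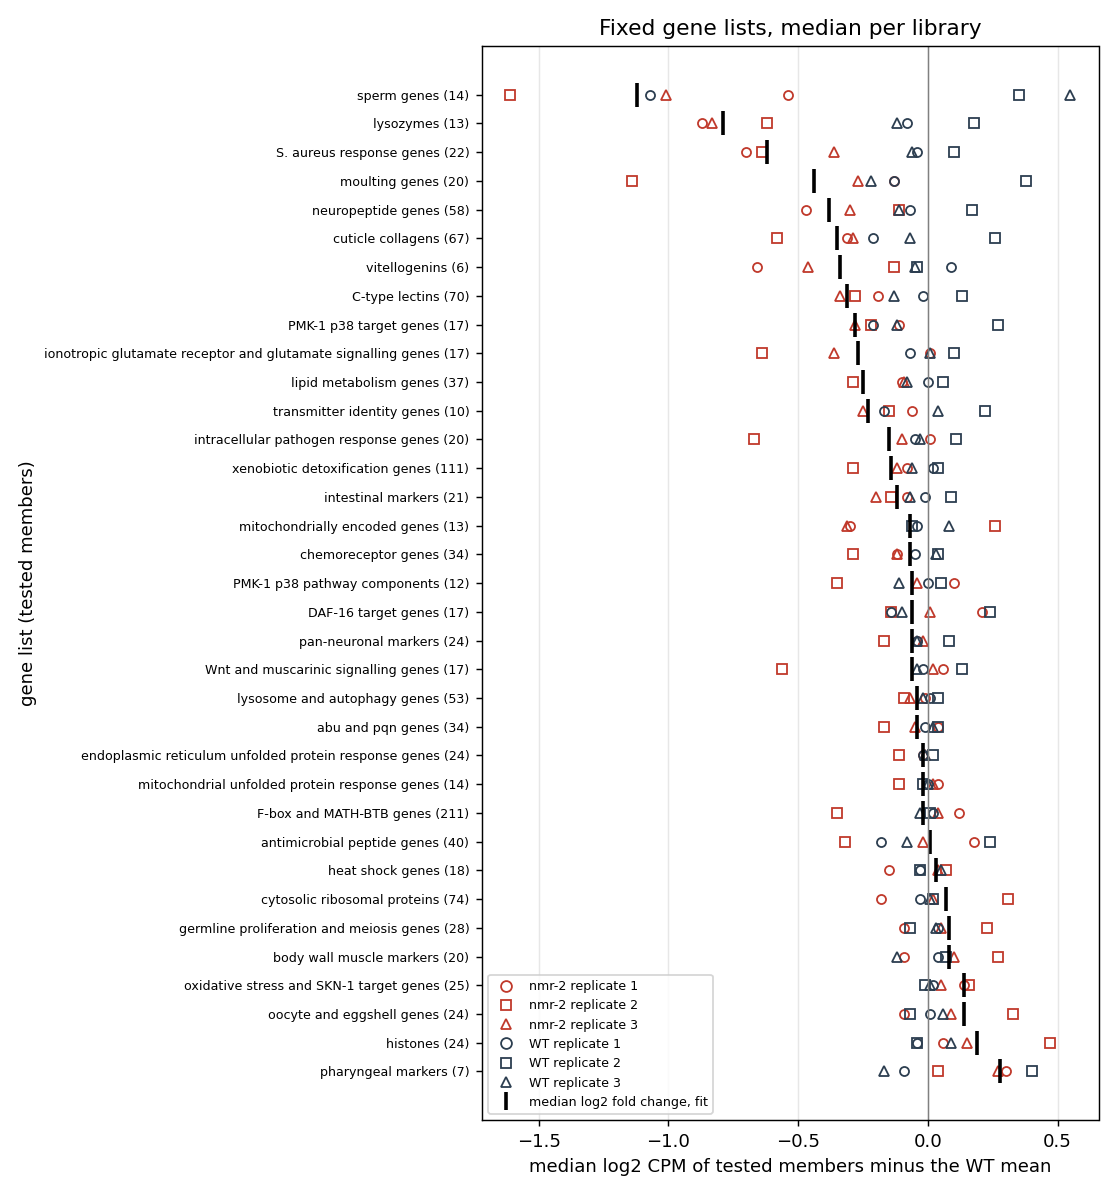
Median log2 CPM of the tested members of each gene list minus the WT mean (x axis, log2 units), per library, with the number of tested members in brackets. Red symbols are nmr-2 libraries, dark symbols are WT libraries, and black bars are the median log2 fold changes of the fit; for the lysozymes the nmr-2 libraries sit at −0.87, −0.62 and −0.83 and the WT libraries between −0.12 and 0.18.

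Changed genes were concentrated on chromosome V, the chromosome that carries nmr-2. It held 45 of them, 42 of these lower, among them lys-1, lys-2, fat-5, gid-7, lipl-3, cpl-1 and icl-1. That is 43.3% of the changed genes against 18.1% of the tested genes (odds ratio 3.52, 95% interval 2.32 to 5.29; Fisher's exact test, two-sided, p = 2.86e-09, adjusted over the 6 chromosomes p = 1.72e-08). Chromosomes I and III held fewer than their share, with 7 and 8 changed genes (odds ratios 0.345 and 0.407; Fisher's exact test, adjusted p = 0.00755 and 0.0169). Chromosomes II, IV and X held 11, 22 and 11 and did not pass (adjusted p = 0.103, 0.214 and 0.326). Within 2 Mb of nmr-2, 7 of 406 tested genes changed, or 1.72%, against 0.884% elsewhere (odds ratio 1.97, 95% interval 0.765 to 4.25; Fisher's exact test, p = 0.101). Leaving out a library gave odds ratios from 0.617 to 1.29 for that window, on both sides of 1. A window of 5 Mb passed, with 21 of 1034 genes (odds ratio 2.56, 95% interval 1.5 to 4.2; Fisher's exact test, p = 4.18e-04). Neighbouring genes are not independent units, so these p-values are too small to be taken at face value. The odds ratio for chromosome V was lower whenever a library was left out, between 1.72 without nmr-2 replicate 2 and 2.85 without nmr-2 replicate 3, and stayed above 1 in all 6 of these fits (highest p = 0.0227, Fisher's exact test).

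**Figure D3:**
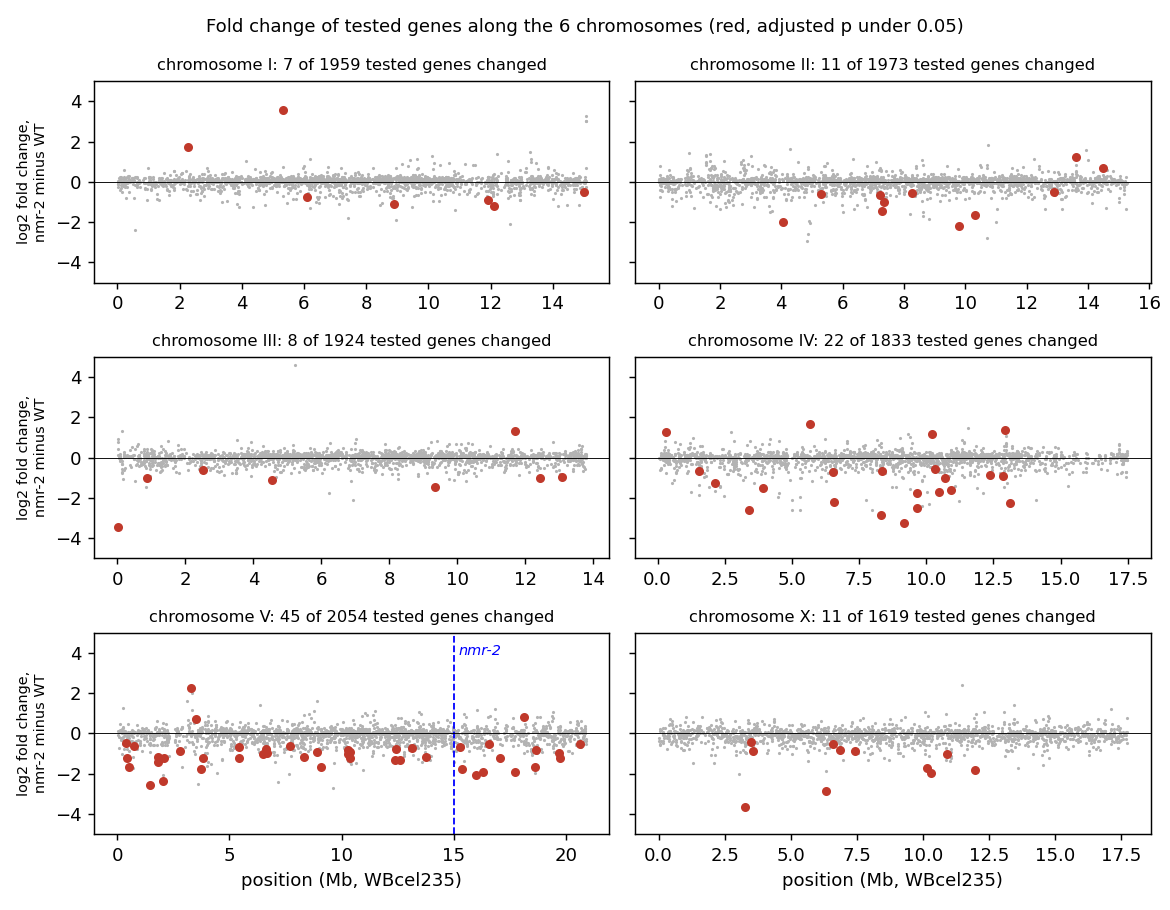
Log2 fold change of each tested gene, nmr-2 minus WT (y axis), against its position in Mb on the 6 nuclear chromosomes of WBcel235 (x axis). Red points are genes with adjusted p under 0.05, grey points are the other tested genes and the dashed line marks nmr-2; the 45 red points of chromosome V lie along its whole length.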

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

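The fits with the ribosomal RNA share as a covariate and with ribosomal RNA genes removed were chosen only after the result was seen, as were the alternatives for chromosome V. Every one of the 92 lower and 12 higher genes that was tested in an alternative kept its direction there. The groups did not overlap in any of these genes, so leaving out a library could hardly have turned a direction. The kept directions are therefore little evidence of robustness. Over the alternatives, the 118 named genes gave 1593 values on the same side of the threshold, 161 that lost the call and 12 that gained it, and no call changed direction. Only the 45 named genes called in the first fit could lose a call, and the 1593 include values of uncalled genes that stayed uncalled. The number of changed genes stayed within 1.5 times of that with RLE (110, of which 98 shared), limma-voom (98, 96 shared), a minimum of 1 CPM (90, 89 shared), upper-quartile normalisation (80, 71 shared) and removal of ribosomal RNA genes (105, with all of the first fit's genes shared). It rose to 275 (57 higher, 218 lower) with DESeq2 and to 646 (135 higher, 511 lower) with no filter, among 19851 tested genes, the 646 including all genes called with the filter. It fell to 23 (3 higher, 20 lower) against a 1.5-fold change and to 26 (4 higher, 22 lower) with the ribosomal RNA covariate. With that covariate the changed genes' median size of log2 fold change was 1.06 against 1.17 and their median standard error 0.22 against 0.17, and the ratio of the folds had quartiles of 0.805 and 1.01. The lower share was 88.5%, against 79.1% with no filter and 79.3% with DESeq2. Leaving out a library gave from 33 to 489 changed genes, 5 to 135 higher and 26 to 354 lower. Dropping nmr-2 replicate 2 gave the highest count although it leaves fewer libraries, with 72.4% lower. The causes of the other shifts were not tested beyond the tests on that library given further on.

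Same-numbered libraries did not deviate together (correlations −0.19, −0.31 and −0.1). Deviations were taken from the group means, and nmr-2 replicate 2 weighed heavily on those of its group (−0.82 and −0.59 with replicates 1 and 3). A pairing by number is therefore neither shown nor excluded. With the replicate number as a block, 87 genes changed (17 higher, 70 lower), 73 of them shared with the fit without it. The block ended 1 list call, that of the germline proliferation genes (median 0.08, adjusted p = 0.0588), and changed no other.

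With an estimated correlation camera called 0 lists lower and 0 higher. This ended the calls of the S. aureus response genes (median −0.62), lysozymes (−0.79), oxidative stress genes (0.14), C-type lectins (−0.31), detoxification genes (−0.14), moulting genes (−0.44), glutamate signalling genes (−0.27), neuropeptides (−0.38), sperm genes (−1.12), oocyte genes (0.14), vitellogenins (−0.34), germline genes (0.08), lipid metabolism genes (−0.25), ribosomal proteins (0.07), histones (0.19) and chemoreceptors (−0.07). Fry ended the same calls except the first 3, leaving 2 lists lower and 1 higher. Correlated members do not account for every call that camera lost. The oxidative stress and chemoreceptor lists had estimated correlations of −0.03 and 0, not above the preset 0.01. Their unadjusted camera p still rose from 0.00215 to 0.0269 and from 0.00435 to 0.0368.

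With no filter the detoxification (−0.13, adjusted p = 0.128) and glutamate (−0.22, 0.174) calls were lost, camera's direction for the chemoreceptors turned upward (median −0.05, 0.939), the collagens were called lower (−0.75, 0.00129) and the sperm median was −2.06. The uncalled pharyngeal median was −0.28 with no filter (camera's direction down, adjusted p = 0.853), against 0.28 with the filter. With the ribosomal RNA covariate 3 lists were higher. Calls were lost for detoxification (−0.01), moulting (−0.07) and glutamate signalling (−0.14) and gained for collagens (−0.39), transmitter identity (−0.20), intestinal markers (−0.15), pharyngeal markers (0.53) and mitochondrially encoded genes (−0.49). Lipid metabolism genes stayed called at −0.07 (adjusted p = 0.0373) and vitellogenins at −0.57. Among lists called in either fit, the direction turned for oocyte genes (−0.06), germline genes (−0.05), ribosomal proteins (−0.13), histones (−0.03) and F-box genes (0.13). The cause of these list shifts was not tested.

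Leaving out a library left 2 to 5 lists higher, and the medians of lists whose call moved ran as follows. Collagens ran from −0.81 to −0.19, moulting genes from −0.73 to −0.23, glutamate signalling from −0.45 to −0.14, chemoreceptors from −0.21 to −0.07 and intestinal markers from −0.20 to −0.06. Sperm genes, called in each fit, ran from −2.96 to −0.92 and C-type lectins from −0.37 to −0.17. Oocyte genes ran from 0 to 0.25, histones from 0.10 to 0.32, pharyngeal markers from −0.07 to 0.35 and mitochondrially encoded genes from −0.34 to 0.02. Among lists called in either fit, the direction turned without nmr-2 replicate 2 for germline genes (−0.01 to 0.15), ribosomal proteins (−0.08 to 0.19) and F-box genes (−0.11 to 0.06). Directions of lists called in neither fit turned as well, as for the DAF-16 targets (0.10 without nmr-2 replicate 2) and PMK-1 targets (−0.06 without WT replicate 2). Other uncalled medians ran from −0.13 to −0.03 for PMK-1 pathway components, −0.14 to −0.02 for abu and pqn genes, −0.03 to 0.09 for heat shock genes and −0.03 to 0.02 for mitochondrial unfolded protein response genes. Widening the window around nmr-2 to 5 Mb gave an odds ratio of 2.56, past the threshold, against 1.65 for 1 Mb.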

Other observations

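The tests of single-library, intestinal and stage explanations for the S. aureus genes, of linkage within 5 Mb of nmr-2 and of library pairs without ribosomal RNA were chosen only after the result was seen, as were the gene families and genes named in the next paragraph. The counts of splits, the test outside gene families, the dispersion test and the number of genes detected after thinning were set before their results were seen. For the dispersion test, the bound set beforehand was met, and the comparison of intervals used for it below was chosen after its result.

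Some gene families sharing a symbol stood out among the lowered genes. Of 143 families of at least 8 tested genes sharing a symbol, 5 held more lowered genes than the rest (Fisher's exact test, one-sided, adjusted over the families). Cathepsin B-like genes gave 3 of 8 (adjusted p = 0.00281), namely cpr-4, which was at 528 ± 33.7 CPM in nmr-2 and 901 ± 38.6 CPM in WT, cpr-3 and cpr-6; cpr-4 was called in all 6 fits that left out a library and the other genes in 2 each. Acyltransferase-like oac genes gave 3 of 10 (adjusted p = 0.00281), namely oac-6, oac-14 and oac-20, called in 1, 4 and 2 of those fits. The others were lys (3 of 9, 0.00281), clec (5 of 70, 0.00885) and ugt (4 of 45, 0.0132), whose genes are also in the lysozyme, lectin and detoxification lists above. Members of a family are not independent units, so these p-values cannot be taken at face value. Other single lowered genes follow, with no test of a shared function. The phosphoethanolamine methyltransferase gene pmt-1 was at 311 ± 31.8 against 479 ± 22.3 CPM (edgeR adjusted p = 0.0191; called in 2 of the 6 fits), and the histidine ammonia-lyase gene haly-1 at 10.9 ± 0.76 against 21.7 ± 1.5 CPM (edgeR adjusted p = 0.00379; called in all 6). The gene msra-1, for a methionine sulfoxide reductase, was at 12 ± 0.97 against 23.6 ± 3.12 CPM (edgeR adjusted p = 0.00765; called in 5).

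The labels give the L4 stage at the start of infection, and no stage at collection. Vitellogenin transcripts are known from adults and msp transcripts from animals making sperm. Every library held many vitellogenin reads and few msp reads, which argues against L4 animals at collection, although the exact stage is uncertain. The msp genes are near-identical copies whose reads may have been lost in counting, so their low counts are weak evidence. Vitellogenin genes took 9.77%, 11.6% and 10.9% of the reads in the nmr-2 replicates and 14.8%, 13.9% and 13.7% in WT. Major sperm protein (msp) genes summed to 8.63, 1.4 and 3.52 CPM in the nmr-2 replicates and to 3.86, 28.9 and 40.6 CPM in WT. The adult collagen gene col-19 was at 182, 259 and 243 CPM in nmr-2 and 150, 156 and 131 CPM in WT. Its direction was opposite to that of the vitellogenins. Eggshell cpg genes summed to 4670, 5220 and 5240 CPM in nmr-2 and 4370, 4460 and 4780 CPM in WT, so the groups overlapped. These msp, col-19 and cpg values are without TMM scaling. With TMM scaling cpg-2 was at 2400, 3330 and 2870 CPM in nmr-2 and 2400, 2440 and 2610 CPM in WT. In nmr-2 replicate 1 the eggshell genes were therefore not clearly opposite to the vitellogenins.

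The S. aureus response genes lay lower in nmr-2 with a median log2 fold change of −0.62. The library rich in ribosomal RNA is not the whole source, since without it the median was −0.52 and 78.3% of the members lay below 0. A smaller intestinal share of the RNA would lower the 21 intestinal markers as much, but the response list lay lower than these by −0.5 on the log2 scale (95% bootstrap interval over genes −0.86 to −0.18). That interval takes genes as independent and leaves out the spread between libraries. The marker median itself was −0.12, and that of the vitellogenins, made by the adult intestine, was −0.34. An intestinal part of the difference is therefore not excluded. An offset in developmental stage cannot be told apart from an effect of nmr-2, because oocyte and eggshell genes lay on the other side of the WT mean from vitellogenins in only 2 of the 3 nmr-2 libraries, and each genotype was sampled at 1 stage. Lower induction by S. aureus, lower levels before infection and other variants of the mutant strain remain open, and no uninfected animals were analysed here.

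Of the 10 ways to split the 6 libraries into 3 and 3, 1, the real one, called 12 genes higher and 92 lower, and the highest count of the others was 0. The splits are too few for a share under 0.05.

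The changed genes were concentrated on chromosome V (odds ratio 3.52). Variants linked within 5 Mb of nmr-2 do not account for it alone, because the part of the chromosome beyond 5 Mb gave an odds ratio of 3.78 against the other chromosomes (95% interval 2.24 to 6.21). The defence and detoxification genes in the 35 lists and in families of 8 or more do not either, because genes outside these gave 3.01 (95% interval 1.63 to 5.43). Defence and detoxification genes of smaller families, or without a family name, were not removed and may still contribute. General variability of its genes cannot be told apart from an effect of genotype. The same number of genes, taken as those with the highest dispersion within groups relative to the trend with expression, gave 1.52 (95% interval 0.933 to 2.4). The upper limit lies below 3.52, which was the bound set beforehand, but the interval overlaps the 2.32 to 5.29 of the changed genes. The genes called without nmr-2 replicate 2 or WT replicate 1, other sets of 489 and 71 genes, gave 1.72 and 1.9, inside 0.933 to 2.4. A hypothesis left open is that variants elsewhere on the mutant's chromosome V, or a regulator acting on many of its genes, may contribute; neither was tested.

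The library of nmr-2 replicate 2 stood apart from the other 5, with 7.48% ribosomal RNA, and 489 genes were called without it, against 12 higher and 92 lower with it. Displacement of messenger reads by ribosomal RNA would scale all other genes alike, but over 11374 tested genes outside ribosomal RNA its correlations with the other nmr-2 libraries were 0.9869 and 0.9906, below the 0.9947 to 0.9952 of the other pairs within a group. Fewer messenger reads do not account for it either, since after thinning to 18562914 reads its lowest chi-square per degree of freedom against another nmr-2 library was 20.3, over 5 draws, and the highest of the other pairs 11.4. The number of genes with a read after thinning, 15020 against 15662 to 16671, lay below the others by less than their range and decided neither way. A state of the RNA or of the animals that went with the ribosomal RNA share stays open. The fall to 26 calls with that share as a covariate cannot decide it. The share was 1.57%, 7.48% and 0.603% in nmr-2 and 0.199%, 0.329% and 0.66% in WT, so it partly follows genotype. That alone can widen standard errors, whose median was 0.22 against 0.17. The changed genes' median size of log2 fold change stayed at 1.06 against 1.17, but these genes were chosen for differing by genotype. The median of ribosomal proteins moved from 0.07 to −0.13 with the covariate and to −0.08 without this library. That of PMK-1 targets moved from −0.28 to −0.56 and −0.22. No biological explanation was tested for this library.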
